A study of Mus musculus with 6 samples.

How the data were processed

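Perihematomal brain tissue, the tissue around the blood clot, was taken from mice on day 5 after an experimental intracerebral haemorrhage (ICH, bleeding into the brain). Per the labels' protocols the mice had received TEPP-46 or vehicle on consecutive days after the bleed, and total RNA was turned into cDNA, amplified by PCR and made into libraries with a nanopore cDNA-PCR kit. TEPP-46 is a small molecule that activates the M2 form of pyruvate kinase, the enzyme that Pkm encodes. The series holds 3 TEPP-46 and 3 vehicle samples. Nothing in the labels says that the samples of a group came from separate animals, so p-values measure the spread between these samples.

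The authors deposited 2 tables, per the file headers, one of genes and one of isoforms, with raw counts for each library. CPM, the raw count scaled by the library's total in the same table, was computed here from the counts; 12 other columns with values per library were not used. The authors also deposited p-values, log2 fold changes and a call per gene or isoform, with DESeq2 named per the file headers, while the submitters' processing notes name DESeq 1.10.1 and the build GRCm38. Per the file headers, the authors' gene calls used an unadjusted p of 0.01 and a fold of 1.5, and their isoform calls a false discovery rate of 0.05 and a fold of 1.5. The p-values and log2 fold changes in the authors' deposited table were used only where they are named as such. The aligner, the counting tool and the treatment of reads matching several isoforms are not given in the sources used here.

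The columns are headed C1, C2, C4 and T1, T2, T3. The letter ties a column to vehicle (C) or TEPP-46 (T), but the column numbers do not match the numbered samples, so libraries are named by their column and were treated as replicates without an order. That the letters stand for these groups follows from the 2 group names only. The sign of the authors' log2 fold change was T over C when checked against the counts.

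Counts were given for 24459 genes, 2180 of them new loci, and for 75457 isoforms, 10082 of them new without a reference identifier. Gene counts equalled the sum of their isoform counts in 99.9% of genes. Isoform counts within a gene were closer to each other than independent counts can be. Of 2119 genes whose 2 most abundant isoforms had a mean count of 100 or more, 57.0% of the pairs were closer than 95% of independent counts would be, where 5% would be expected. Isoform counts of a gene are therefore not independent of each other. Whether a read was counted more than once or divided between isoforms was not tested, and intervals based on counts treat them as independent reads and cover counting error only.

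Genes were tested with edgeR 4.0.16 in R 4.3.3. The low-count filter was filterByExpr, the scaling TMM, and the test the quasi-likelihood F test with robust empirical Bayes and group as the single term, without a block. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The same fit was used for isoforms. Isoform usage, the proportions of a gene's isoforms apart from its total, was tested with diffSpliceDGE of edgeR and Simes p-values per gene. The standard errors of log2 fold changes were derived from the fitted value and its F statistic.

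Before the data were examined, 36 lists of cell type markers and pathway genes, the tests, the rule for naming genes and most of the other settings were fixed. Lists with at least 5 tested members were tested with camera of limma 3.58.1 on voom values with a preset correlation of 0.01, and again with an estimated correlation and with fry. The pathway annotation of the deposited gene table was tested in the same way for terms with 10 to 300 tested genes. Gene symbols are those of the files, and a symbol carried by 2 identifiers counts as 2 entries.

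The naming rule took the 10 genes with the largest and the 10 with the lowest log2 fold change among called genes with non-overlapping groups, filled up by the smallest unadjusted p where fewer passed. It took called members of each list, or the 2 members with the highest mean CPM where none were called, and Pkm. No gene was called, so all 20 genes were chosen by unadjusted p and did not pass. Genes named outside the rule were chosen after their values were seen and are said to be so. Some genes that the rule took are not reported here.

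The Pkm isoforms Pkm-201 and Pkm-202 were matched by transcript identifier to the reference annotation of GRCm38. Pkm-201 holds the M2 exon (chromosome 9, 59675568 to 59675734) and Pkm-202 the M1 exon (chromosome 9, 59675029 to 59675195), both 167 bases long and inside the coding part of Pkm. The M2 share is the count of Pkm-201 over the sum of both. Groups were compared with an exact two-sided permutation test, whose smallest possible p with 3 against 3 is 0.1. Intervals of a share are exact binomial intervals at 95%.

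The gene test was tested on simulated data: 10 draws of 14441 genes for TEPP-46 against vehicle, with the real means, library sizes and dispersions and 200 changed genes. With edgeR, 83.0% of genes changed 4-fold, 35.2% of genes changed 2-fold and 3.43% of genes changed 1.5-fold were recovered, and 8.38% of calls were false on average. DESeq2 1.42.0 recovered 85.3%, 42.7% and 9.70% of the same genes with 16.7% false calls. With no gene changed, edgeR made 0 calls in all 10 draws and DESeq2 4.7 on average, with at most 12. In the same kind of simulation, camera called a planted list of the 31 lists drawn and no other, and the usage test, run on 7434 genes, recovered 99% of 100 genes whose 2 leading isoforms were exchanged, with 1 false call. The exchanged isoforms were chosen to be well counted and clearly different in level, so recovery of a small change in a rare isoform was not tested. Simulated genes and isoforms were drawn independently of each other. The simulation therefore does not show how camera or the usage test behave with correlated genes or isoforms. In the data the estimated correlation was 0.947 for the myelin list and 0.709 for the choroid plexus list.

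The other settings were other scalings, no filter or a filter on the mean count, DESeq2, limma-voom, a fit without robust empirical Bayes, a block for column numbers, removal of haemoglobin and mitochondrial genes, annotated features alone, and leaving out each library in turn. Settings meant for normalized values did not apply, since the tables hold counts. Settings added after seeing the data were a gene count taken from the highest isoform and an offset for GC content and transcript length.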

Results

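RNA from perihematomal brain tissue of mice on day 5 after intracerebral haemorrhage was counted from long reads in 3 libraries of TEPP-46-treated and 3 of vehicle-treated mice. Total gene counts per library were between 5286426 and 6025064. They averaged 5.44226e+06 ± 225314 in vehicle and 5.6515e+06 ± 359911 in TEPP-46 (SD, n = 3 each; exact two-sided permutation p = 0.6). Between 18429 and 18985 genes had a count in a library. Haemoglobin transcripts, a sign of blood in the tissue, took 0.0609 ± 0.0389% of counts in vehicle and 0.0649 ± 0.00944% in TEPP-46 (SD, n = 3 each; exact two-sided permutation p = 0.9). The Y-linked genes Ddx3y and Eif2s3y had similar counts in all 6 libraries, 145 to 181 and 129 to 152.

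The comparison asks which transcripts differ in the tissue around the clot when pyruvate kinase M2 is activated by TEPP-46. No gene of the 14441 tested was called by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and the smallest adjusted p was 0.380. At an unadjusted p under 0.05, 271 genes were higher and 585 lower in TEPP-46, where chance gives 722 in all. At an unadjusted p under 0.01 the counts were 40 higher and 183 lower, where chance gives 144. These counts moved with single libraries: under 0.05, 526 genes were higher and 500 lower without vehicle library C1, and 665 and 836 without C2. DESeq2 called 3 genes higher and 85 lower, and without vehicle library C2 edgeR called 2 higher and 41 lower. In 11.4% of tested genes the 3 TEPP-46 libraries did not overlap the 3 vehicle libraries, where chance gives 10%.

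The 10 genes with the smallest unadjusted p among those higher in TEPP-46 did not pass in edgeR. Slc6a11 (chromosome 6, 114131241 to 114249952), the astrocyte GABA transporter GAT-3, was at 46.0 ± 5.48 CPM in TEPP-46 and 24.1 ± 0.781 in vehicle (SD, n = 3 each), a log2 fold change of 0.92 with SE 0.16 and an edgeR adjusted p of 0.380. Zic1, a zinc finger transcription factor, was at 14.7 ± 0.702 against 6.72 ± 1.80 CPM, and Zbtb7b, another transcription factor, at 16.6 ± 2.04 against 7.96 ± 0.103 CPM. Cdh8, a cadherin of neurons, was at 23.3 ± 1.51 against 13.3 ± 1.81 CPM, and Fam107a, an actin-associated gene of astrocytes and neurons, at 529 ± 48.3 against 381 ± 24.8 CPM. Lbhd2 was at 8.77 ± 0.937 against 2.31 ± 0.762 CPM and Als2cl at 10.2 ± 2.70 against 2.78 ± 1.47 CPM. Parp16, an ADP-ribosyltransferase of the endoplasmic reticulum, was at 10.7 ± 2.27 against 4.14 ± 1.04 CPM, and the F-box gene Fbxw17 at 15.2 ± 1.78 against 7.06 ± 0.690 CPM. Lrmda rested on 42 counts in TEPP-46 and 11 in vehicle.

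Genes at the other end, lower in TEPP-46, did not pass in edgeR either, each with an adjusted p of 0.380. Tmem160 (chromosome 7, 16452779 to 16455494) was at 12.6 ± 2.57 CPM in TEPP-46 and 71.0 ± 41.0 in vehicle (SD, n = 3 each), with 32.1 CPM in C2 and 114 in C4. Lrp11, of the LDL receptor family, was at 39.8 ± 8.66 against 93.6 ± 14.8 CPM, a log2 fold change of -1.25 with SE 0.19. Ak5, an adenylate kinase of the brain, was at 53.5 ± 13.1 against 125 ± 25.9 CPM. Wrnip1, which binds the Werner helicase, was at 6.48 ± 1.12 against 21.0 ± 5.55 CPM, Prrt3 at 17.1 ± 5.23 against 54.5 ± 18.1 CPM, and Mcrip1 at 62.9 ± 6.33 against 109 ± 16.1 CPM. Counts were low for Tmem238, with 5 in TEPP-46 and 70 in vehicle, and for Tspan8, a tetraspanin, with 2 and 39. Scaled by the total counts of each group, the Tspan8 count ratio was 0.0494 with an exact 95% interval of 0.00578 to 0.191. Vmn2r105, with 11 and 70 counts, belongs to the large family of vomeronasal receptors and is uncertain where reads are shared between its members. Of the genes named here DESeq2 called Lbhd2, Slc6a11, Als2cl, Lrp11, Wrnip1, Ak5, Prrt3, Vmn2r105, Tmem160, Mcrip1 and Tmem238.

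**Figure D1:**
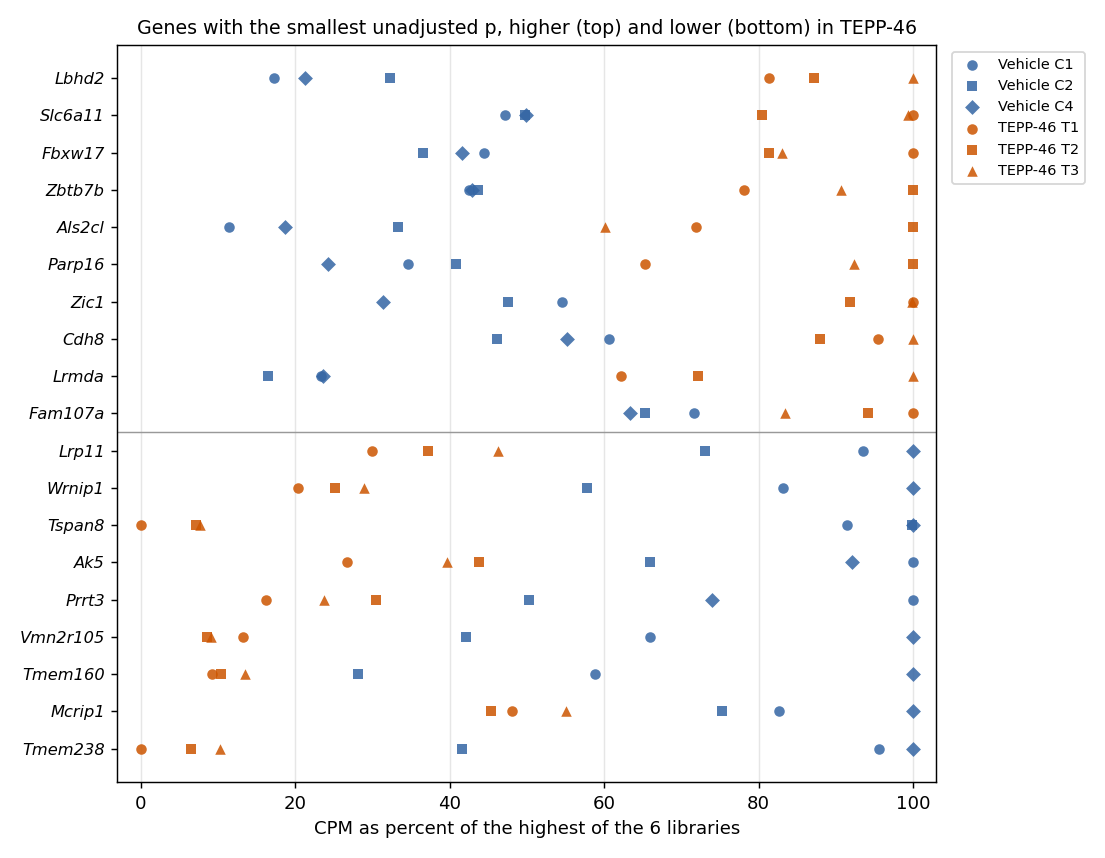
CPM of the genes named above in each library as a percent of the gene's highest library (horizontal axis), with vehicle libraries in blue and TEPP-46 libraries in orange. The groups do not overlap in any of these genes because they were chosen by the smallest unadjusted p; of the vehicle libraries C2 lies nearest to TEPP-46 in most of the lower genes.

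The authors' deposited table lists 20 genes as higher and 205 as lower in TEPP-46. Per the authors' deposited table, a p under 0.01 was reached by 313 of 15896 genes, where chance gives 159, and 77 pass when its p-values are adjusted by Benjamini-Hochberg. All 20 listed as higher and all 203 listed as lower in the authors' deposited table that edgeR tested reached an unadjusted p under 0.05 in edgeR. Across genes, which are not independent replicates, the log2 fold changes of the authors' deposited table and of edgeR had a Spearman correlation of 0.986. For Tmem160 the authors' deposited table gives a log2 fold change of -1.51 where edgeR gave -2.51.

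Markers of the choroid plexus and ependyma, which line the ventricles, were higher in TEPP-46 as a list. All 12 tested members had a positive log2 fold change, with a median of 0.86, and the camera test of limma with a preset correlation passed (adjusted p = 6.57e-09). Its adjusted p = 0.972 with an estimated correlation, and no member passed on its own, adjusted over all genes or adjusted over the list alone. The level of Ttr, the transthyretin gene of the choroid plexus, was 2697 ± 796 CPM in TEPP-46 and 1356 ± 2336 in vehicle (SD, n = 3 each), with 4053 CPM in C1, 0.526 in C2 and 13.6 in C4. Enpp2 was at 646 ± 183 against 416 ± 402 CPM. The list without any single library still passed with a preset correlation. Tcf7l2, a marker of the thalamus chosen after its values were seen, was at 69.5, 15.6 and 4.35 CPM in C1, C2 and C4 and at 95.1, 36.6 and 62.7 in T1, T2 and T3.

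Genes of oligodendrocytes and myelin were the second list that passed. All 14 tested members had a positive log2 fold change, between 0.27 and 0.52, with a median of 0.36 and a preset-correlation adjusted p of 2.33e-05 (limma camera). That call had adjusted p = 0.972 with an estimated correlation, and adjusted p = 0.348 without vehicle library C4. Mbp, the myelin basic protein gene, was at 3747 CPM in C4 and between 8850 and 10690 CPM in the 5 other libraries. Oligodendrocyte precursor genes such as Bcas1 (160 ± 19.7 against 116 ± 58.2 CPM, SD, n = 3 each) and Ptprz1 (38.8 ± 2.04 against 32.7 ± 5.07 CPM) had a median of 0.23 and did not pass (adjusted p = 0.177).

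Genes of striatal projection neurons, the main neurons of the striatum, had a median log2 fold change of 0.19, with 12 of 14 members positive and a preset-correlation adjusted p of 0.0254 (limma camera). This call had adjusted p = 0.972 with an estimated correlation. It turned to the other direction without C1 (adjusted p = 0.926) and did not pass without C4 (adjusted p = 0.0537) or T2 (adjusted p = 0.402). Penk, the proenkephalin gene, was at 609 ± 113 CPM in TEPP-46 and 526 ± 358 in vehicle, and Ppp1r1b at 309 ± 21.5 against 269 ± 110 (SD, n = 3 each). Cortical excitatory neuron genes had a median of -0.19 (adjusted p = 0.213), with Slc17a7 at 300 ± 83.5 against 328 ± 90.6 CPM. In that list Neurod2, a neuronal transcription factor, passed adjusted over the list alone, with 8.41 ± 2.12 CPM in TEPP-46 and 23.6 ± 9.76 in vehicle (log2 fold change -1.50, SE 0.34), and not over all genes (edgeR adjusted p = 0.387). DESeq2 called Neurod2 over all genes (adjusted p = 0.0132), as did edgeR without C2 (adjusted p = 0.0354); it was chosen after its values were seen. General neuron genes had a median of 0.06 (adjusted p = 0.713), with Nrgn at 2611 ± 191 against 3128 ± 573 CPM and Syt1 at 1778 ± 393 against 1563 ± 248.

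**Figure D2:**
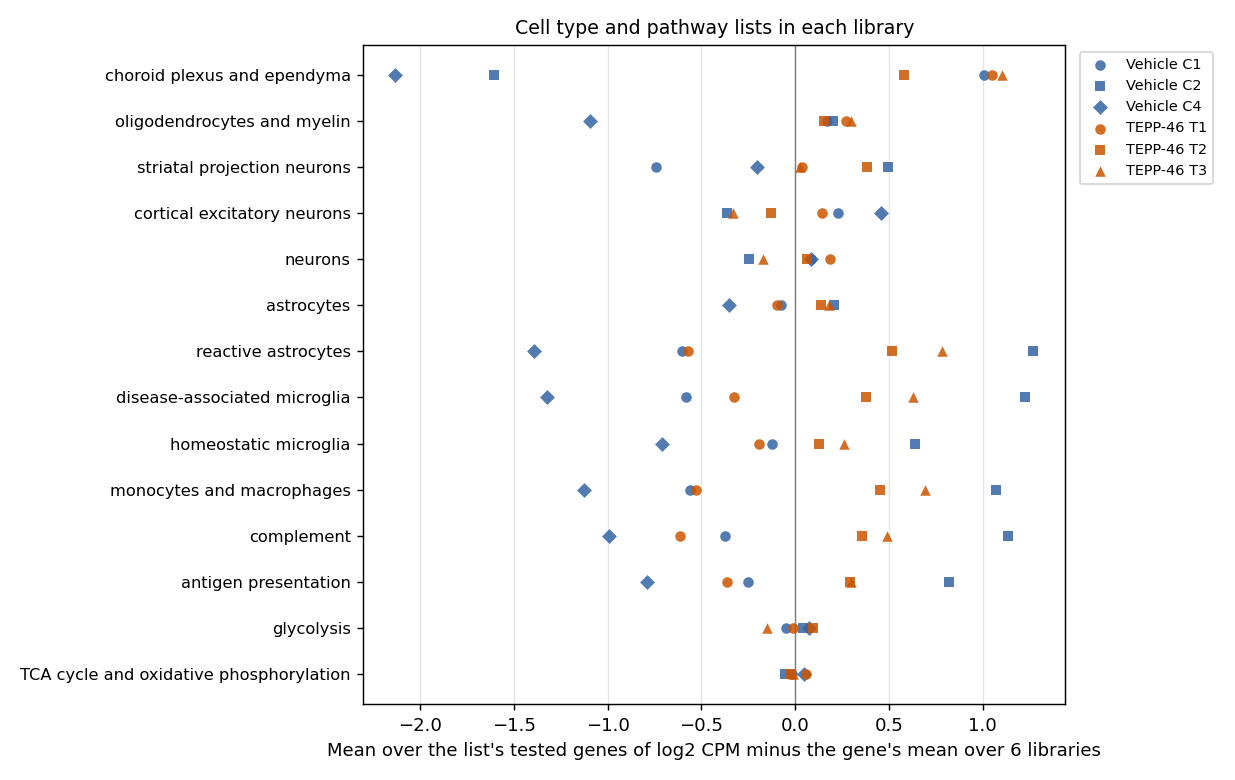
Mean deviation of each list's genes in each library (log2 CPM minus the gene's mean over 6 libraries, horizontal axis) for 14 lists, vehicle libraries in blue and TEPP-46 libraries in orange. C2 is highest and C4 lowest of the 6 in the disease-associated microglia list (1.23 and -1.32), while glycolysis lies between -0.15 and 0.10 in all 6 libraries.

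Lists of microglia, macrophages and inflammation did not pass with all libraries, and their vehicle libraries were far apart. Genes of disease-associated microglia had a median log2 fold change of 0.02 (adjusted p = 0.105). Of these, Apoe was at 10715 ± 2593 CPM in TEPP-46 and 10942 ± 4759 in vehicle, and the lysosomal protease gene Ctsd at 1746 ± 563 against 1634 ± 1584 (SD, n = 3 each). Homeostatic microglia genes had a median of 0.04 (adjusted p = 0.849), with Bin1 at 172 ± 22.7 against 199 ± 15.2 CPM. Pro-inflammatory mediators had a median of 0.08 (adjusted p = 0.177), with the Fc receptor gene Fcgr3 at 61.7 ± 18.6 against 68.1 ± 52.6 CPM and Il18 at 52.8 ± 9.44 against 57.5 ± 14.2, and anti-inflammatory and repair mediators a median of 0.11 (adjusted p = 0.687), with Vegfb at 60.5 ± 16.9 against 97.0 ± 26.7 CPM. Lysosome and phagocytosis genes had a median of 0.05 (adjusted p = 0.216), with Psap at 5150 ± 127 against 5069 ± 700 CPM and Ctss at 365 ± 83.6 against 360 ± 285. The median was 0.09 for monocytes and macrophages (adjusted p = 0.213), with Lyz2 at 162 ± 85.7 against 193 ± 268 CPM, and -0.01 for border-associated macrophages (adjusted p = 0.690), with Pf4 at 9.01 ± 5.25 against 12.7 ± 14.3 CPM. For that last list camera's direction was up against a median below 0. Complement genes had a median of -0.21 while camera's direction was up (adjusted p = 0.910), with C1qc at 181 ± 93.8 against 223 ± 176 CPM and C1qb at 181 ± 56.9 against 181 ± 153. The medians were 0.04 for interferon response (adjusted p = 0.272), with Ifit3 at 27.9 ± 9.27 against 28.0 ± 11.6 CPM, and 0.06 for antigen presentation (adjusted p = 0.577), with H2-D1 at 267 ± 35.9 against 232 ± 143 CPM and B2m at 227 ± 34.8 against 197 ± 123. All p-values of lists are from limma camera with a preset correlation. With vehicle library C2 left out, 19 lists passed, 18 of them higher in TEPP-46. Among these were disease-associated microglia (adjusted p = 7.38e-13), lysosome and phagocytosis (5.69e-07), monocytes and macrophages (0.000122), pro-inflammatory mediators (0.000278), homeostatic microglia (0.000729), anti-inflammatory mediators (0.00706), complement (0.00122), interferon response (0.00229) and antigen presentation (4.46e-05). These p-values rest on the preset correlation of 0.01, and no fit without C2 used an estimated one. With all libraries the estimated correlation was 0.886 for disease-associated microglia, 0.819 for complement and 0.767 for antigen presentation. The mean deviation of the disease-associated microglia list was 1.23 in C2, -0.58 in C1 and -1.32 in C4. Without T1, 18 lists passed, 16 of them higher. In the fits without C1, C4 or T2, 2 lists passed each, and 3 passed without T3. Without C4, 17 lists called neither there nor with all libraries took the other direction, and without C1 10 lists did. Lists that passed without C2 were not left out of these counts. Neutrophil, lymphocyte and sex chromosome lists had 3, 2 and 4 tested members and were not tested as lists; Lcn2 of the neutrophil list had between 4 and 228 counts, and the median log2 fold changes of the lists were 0.19, -0.02 and -0.03.

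Astrocyte genes had a median log2 fold change of 0.11 with 11 of 12 members positive and did not pass (camera adjusted p = 0.0840). Slc1a2, the main glutamate transporter of astrocytes, was at 1788 ± 240 CPM in TEPP-46 and 1475 ± 60.6 in vehicle, and Glul, the glutamine synthetase gene, at 608 ± 72.3 against 499 ± 30.0 (SD, n = 3 each). Reactive astrocyte genes had a median of 0.14 (adjusted p = 0.177), with Gfap at 251 ± 95.1 against 217 ± 182 CPM and Serpina3n at 61.6 ± 26.0 against 52.3 ± 59.1. Endothelial genes had a median of 0.01 (adjusted p = 0.601), with Ly6c1 at 80.6 ± 4.18 against 68.4 ± 8.38 CPM, and mural cell and fibroblast genes a median of 0.06 while camera's direction was down (adjusted p = 0.941), with Rgs5 at 38.9 ± 5.65 against 40.3 ± 3.69 CPM. For red blood cells the median was 0.06 (adjusted p = 0.643), with Hba-a2 at 218 ± 31.4 against 208 ± 132 CPM. In the haem and iron list, with a median of -0.01 where camera's direction was up (adjusted p = 0.652), Fth1, a ferritin subunit, was at 3538 ± 377 against 3377 ± 529 CPM. Lrp1, a receptor that takes up haem bound to hemopexin, passed adjusted over the list alone at 51.7 ± 2.99 against 34.7 ± 2.61 CPM and not over all genes (edgeR adjusted p = 0.515), and was chosen after its values were seen. The antioxidant list had a median of 0.00 with camera's direction up and a mean of -0.08 (adjusted p = 0.941). Its members Sod1 (368 ± 11.2 against 311 ± 5.02 CPM) and Gpx4 (794 ± 68.9 against 770 ± 54.3 CPM) did not pass.

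Glycolysis, the pathway of the drug's target, did not pass. The 23 tested entries, Aldoa among them under 2 identifiers, had a median log2 fold change of -0.02 (camera adjusted p = 0.910). Gapdh was at 15315 ± 735 CPM in TEPP-46 and 15308 ± 185 in vehicle (SD, n = 3 each). Medians were 0.06 for the pentose phosphate pathway (adjusted p = 0.643), with Taldo1 at 138 ± 4.94 against 131 ± 16.2 CPM, and 0.04 for the TCA cycle and oxidative phosphorylation (adjusted p = 0.724), with Cox6c at 2314 ± 147 against 2405 ± 290 CPM. The HIF-1 response had a median of 0.17 (adjusted p = 0.220), with Bnip3 at 195 ± 19.8 against 207 ± 37.0 CPM. Cell death (0.01, adjusted p = 0.690), cell cycle (0.04, adjusted p = 0.643), cholesterol and lipid synthesis (-0.09, adjusted p = 0.691), mitochondrially encoded genes (0.07, adjusted p = 0.213), heat shock and dissociation stress (-0.18, adjusted p = 0.137) and immediate early genes (0.24, adjusted p = 0.105) did not pass either. Of these, Hspa8 was at 3185 ± 306 against 3252 ± 313 CPM, Scd2 at 267 ± 18.3 against 236 ± 51.9, mt-Co1 at 4781 ± 346 against 4637 ± 256, Bcl2l1 at 255 ± 38.2 against 261 ± 20.8 and Pcna at 29.1 ± 3.48 against 29.8 ± 2.77. Among the immediate early genes, Egr1 was at 126 ± 24.7 against 104 ± 22.7 CPM.

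Pkm itself (chromosome 9, 59656368 to 59679375) was at 2486 ± 203 CPM in TEPP-46 and 2251 ± 36.5 in vehicle (SD, n = 3 each), with a log2 fold change of 0.13, an SE of 0.10 and an edgeR adjusted p of 0.973. Of the counts of the 2 matched isoforms, the M2 form Pkm-201 took 88.9 ± 1.90% in vehicle and 88.1 ± 1.24% in TEPP-46 (SD, n = 3 each; exact two-sided permutation p = 0.7). Single libraries lay between 87.0% (exact binomial 95% interval 85.3 to 88.6) and 90.8% (89.4 to 92.1). Both isoforms were tested, and neither Pkm-201 (adjusted p = 0.999) nor Pkm-202 (adjusted p = 0.990) passed in edgeR. New isoforms without a reference identifier, 6 in number, held between 85.1 and 87.1% of the Pkm counts in a library, so the M2 share covers a small part of them.

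**Figure D3:**
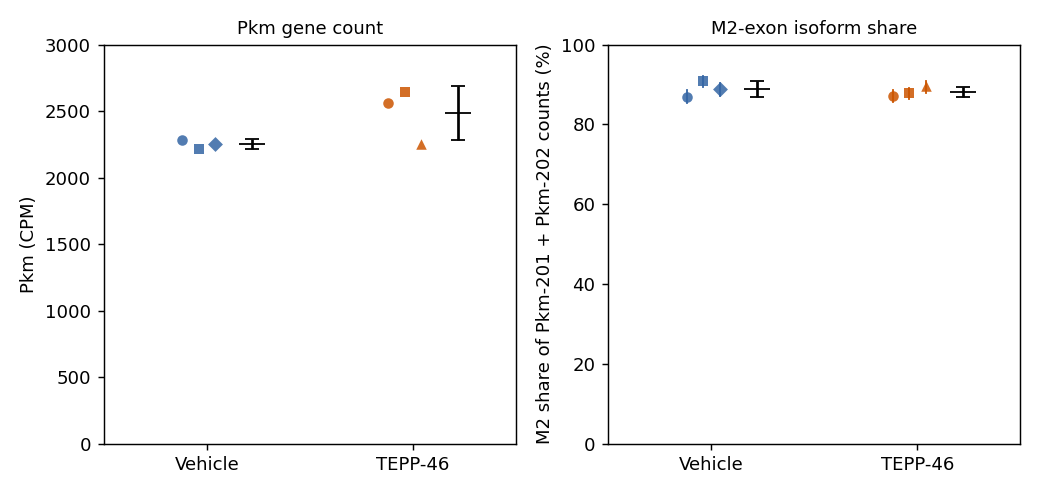
Pkm level in CPM (left) and the M2 share of Pkm-201 plus Pkm-202 counts in percent with exact binomial 95% intervals as thin lines (right), 1 symbol per library, with black marks for the mean and bars for 1 SD (n = 3). Vehicle libraries in blue lie between 2213 and 2286 CPM and TEPP-46 libraries in orange between 2257 and 2643 CPM, and the shares of both groups overlap.

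At isoform level, 0 of 33854 isoforms passed in edgeR, with a smallest adjusted p of 0.254, while 635 were higher and 1319 lower at an unadjusted p under 0.05 where chance gives 1693. DESeq2 called 1 isoform higher and 157 lower, in 117 genes, and the authors' deposited table lists 1 higher and 125 lower, in 100 genes. Without vehicle library C2 edgeR called 2 higher and 176 lower. At an unadjusted p under 0.05, 1203 isoforms were higher and 1405 lower without C1, and 1167 and 1930 without C2.

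Isoform usage differed in 1 of 7639 genes, Srcin1, an adaptor protein of neurons that restrains Src kinase (edgeR diffSpliceDGE, Simes adjusted p = 0.0197). Its isoform Srcin1-207 had 12, 15 and 20 counts in C1, C2 and C4 and 0, 1 and 3 in T1, T2 and T3. It took 4.26 ± 0.986% of the gene's tested counts in vehicle and 0.383 ± 0.471% in TEPP-46 (SD, n = 3 each). The leading isoform Srcin1-203 took 79.0 ± 3.90% and 80.8 ± 2.50%. The call did not pass with a mean count filter of 10, nor without C1 (adjusted p = 0.178), C2 (adjusted p = 0.121), C4 (adjusted p = 0.886), T1 or T2, and isoform counts that are not independent of each other limit this test.

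Of 307 KEGG terms in the deposited annotation 0 passed in limma's camera, and the smallest adjusted p was 0.870. The terms with the smallest p-values were cell adhesion molecules (95 genes, median log2 fold change 0.12) and beta-alanine metabolism (23 genes, median 0.09). Without C2, 12 terms passed, complement and coagulation cascades (adjusted p = 0.000409) and ribosome (adjusted p = 6.09e-05) among them, all higher in TEPP-46.

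The vehicle libraries differed more among themselves than the TEPP-46 libraries did. Correlations of log2 CPM were 0.959 for C1 with C2, 0.961 for C1 with C4 and 0.943 for C2 with C4, against 0.970, 0.965 and 0.976 between TEPP-46 libraries. C2 was closer to T3 (0.974) and T2 (0.971) than to any vehicle library. C1 was also closer to T1, T2 and T3 (0.964, 0.969 and 0.968) than to C2 or C4, while C4 was closest to C1. The leading principal component held 38.5% of the variance and set C4 (-59.5) apart from the other libraries, which lay between -10.9 and 25.3. The groups were not separated by that component.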

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

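The count of 0 called genes held in edgeR under every scaling, filter, block and annotation setting and in limma-voom, with 88 calls in DESeq2 and between 0 and 43 when a library was left out, the 43 without C2; 32 of those 43 were among the 88. Called isoforms went from 0 to 165 without a low-count filter and 158 in DESeq2, and lay between 0 and 178 when a library was left out. Srcin1 was not called with a mean count filter of 10 (0 genes), and leaving out a library gave between 0 and 1 gene. The 3 lists became 0 with an estimated correlation and 0 with fry, and lay between 2 and 19 when a library was left out. KEGG terms lay between 0 and 12. The cause was not tested for any of these. Striatal projection neurons turned to lower without C1, with adjusted p = 0.926, and its adjusted p was 2.87e-09 without C2. The Pkm log2 fold change lay between 0.07 and 0.21 over 19 settings and was not called in any. The M2 share difference lay between -1.68 and 0.23 percentage points when a library was left out, within 1 vehicle SD of the value with all libraries. The 20 named genes kept their direction in all 375 comparisons. This was nearly fixed in advance, since they were chosen by p in these data and their groups do not overlap. They were called in 20 of the 375 comparisons, by DESeq2 or without C2. List members taken by the naming rule, none of them called, kept their direction in 1193 of 1345. Neurod2, outside the rule, was called by DESeq2 and without C2. The highest isoform count per gene and the GC and length offset, chosen after seeing the data, gave 0 called genes, and the offset 4 lists.

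Column numbers 1 and 2 occur in both groups, and their libraries' deviations from the group means correlated at 0.12 and 0.04, so the numbers are not taken to pair them. A replicate block on these numbers gave 0 genes, 35 isoforms, 0 genes with a usage difference, 14 lists and 1 term, with 1 residual degree of freedom. Under the replicate block, lists not called before passed in the opposite direction, lower in TEPP-46: anti-inflammatory mediators, homeostatic microglia and reactive astrocytes (each adjusted p = 0.000726), disease-associated microglia (2.15e-05), lysosome (0.00116), monocytes (0.00415), border-associated macrophages (0.0341), complement (1.40e-05), interferon response (0.0457) and antigen presentation (0.00573). The block also ended the myelin call (0.546), and neurons (0.00116) and immediate early genes (0.000919) passed as higher.

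Depth limits low genes, since 3 counts in a library are 0.498 to 0.567 CPM, and on simulated counts edgeR recovered 35.2% of the genes changed 2-fold.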

Other observations

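Tests of GC content and length, isoform counting, single vehicle libraries, dissected regions and the lists with 1 library left out were chosen after the results were seen. The tests of time of day and of other splits were written down after the gene results were seen and before their own values were computed.

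Single genes of activated microglia and reactive astrocytes, and Hmox1, differed widely between libraries of 1 group. Spp1, the osteopontin gene of activated microglia and macrophages, was at 176 CPM in C1, 3734 in C2 and 108 in C4, and at 362, 1499 and 2220 in T1, T2 and T3. Hmox1, the haem oxygenase gene induced by haem, was at 8.24, 80.3 and 5.49 CPM in vehicle and at 11.1, 52.1 and 68.6 in TEPP-46, in the same order of columns, while the mean deviation of the haem and iron list lay only between -0.28 and 0.31. Gfap ran from 59.4 CPM in C4 to 417 in C2. These genes, other than Gfap, were chosen after their values were seen.

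Some members of the fixed lists reached an unadjusted p under 0.05 without passing, 12 of 445 higher and 8 lower in TEPP-46, where chance gives 22.2 in all. Pfkfb3, whose product makes the activator of phosphofructokinase, was at 17.1 ± 3.59 CPM in TEPP-46 and 9.62 ± 0.808 in vehicle, and Slc4a4, a bicarbonate cotransporter of astrocytes, at 44.7 ± 0.713 against 31.1 ± 3.44 (SD, n = 3 each). Hif1a was at 76.6 ± 5.44 against 61.2 ± 5.00 CPM, while Vegfa was at 7.31 ± 2.60 against 13.1 ± 3.43. The edgeR adjusted p was 0.559 for Pfkfb3, 0.615 for Slc4a4, 0.834 for Hif1a and 0.758 for Vegfa. All 4 were chosen after their values were seen.

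Lower genes outnumbered higher ones by 183 to 40 at an unadjusted p under 0.01. With the GC and length offset the ratio of lower to higher genes was 4.36 (95% of draws over genes 3.18 to 6.46). This argues against GC content or length as the whole cause. From the highest isoform count per gene the ratio was 8.58, which argues against the summing of isoform counts as the whole cause. Reads shared between isoforms stay in that count, so their part was not tested. Clock genes in the phase of Dbp, Dbp itself left out, had a median log2 fold change of 0.12, and those of opposite phase 0.03. The prediction for a different time of collection was a median below -0.5 in the former and a positive one in the latter. Its first part was not met. The cutoff was set here, so a smaller difference in time is not excluded. Dbp itself was at -1.75 (69.3 ± 28.4 CPM in vehicle, 20.8 ± 7.23 in TEPP-46, SD, n = 3 each; edgeR adjusted p = 0.380) and was called by DESeq2 (adjusted p = 0.000209). C2 alone is argued against only as the whole cause. The ratio was 4.575 with all libraries and 1.92 without C2 (1.61 to 2.31), with 340 lower and 177 higher genes. C2 was the highest library in 6.01% of the lower genes. All intervals of these ratios treat genes as independent and do not cover the spread between libraries. Without C4 the ratio stayed at 3.24 (2.24 to 5.15). However, 94 lower and 29 higher genes were then left, fewer in all than the 149 chance gives, and C4 was highest in 79.8% of the lower genes. With no excess of genes left, this ratio cannot decide whether C4 alone carries the imbalance. Without C1 the ratio was 1 (0.76 to 1.32), with 110 lower and 110 higher genes, while C1 was highest in only 14.2% of the lower genes, so whether C1 alone carries the imbalance cannot be told apart from treatment. 

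A different share of choroid plexus, myelin or deep brain regions in the dissected pieces is a candidate explanation for the higher choroid plexus and myelin lists in TEPP-46. Deviations from the group means moved together within both lists, with a median pairwise correlation across genes of 0.816 in the lower of the 2, where 95% of random gene sets stayed under 0.179. Random genes are a weak reference for markers of 1 cell type. Camera's estimated correlation was also high for disease-associated microglia (0.886) and reactive astrocytes (0.820), and low for endothelium (0.154). Moving together therefore does not single out dissection. The myelin call ended in 1 of the 6 fits with 1 library left out, that without C4, and the choroid plexus call in 0 of 6 (adjusted p between 4.52e-16 and 8.43e-05). Each of these fits kept C2 or C4, both low in the choroid plexus list, so they do not test a shift that rests on both. Markers of the thalamus, chosen after their values were seen, had log2 fold changes between 0.40 and 1.12, none of them past the test. Of these, Tcf7l2 was at 69.5, 15.6 and 4.35 CPM in C1, C2 and C4 and at 95.1, 36.6 and 62.7 in T1, T2 and T3. Hypothalamic peptide genes, none past the test either, went both ways, from -0.55 for Pomc to 1.65 for Pmch. Avp, Oxt, Hcrt, Pmch and Gal were lowest in C4, while Agrp, Pomc, Trh and Cartpt were not. Avp, an example chosen after its values were seen, was at 0.757 CPM in C4 and between 59.0 and 130 in the other libraries. An effect of TEPP-46 on these tissues stays open and was not tested apart from dissection.

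With 3 against 3 libraries the 10 possible splits are too few for a share under 0.05, so for none of the following can it be said from them whether chance is excluded. DESeq2's 88 genes compare with 196 in the highest other split, and 2 of the 10 splits gave as many; its 158 isoforms compare with 265, again 2 of 10. The 585 genes lower at an unadjusted p under 0.05 compare with 906 in 1 direction, also 2 of 10. The 3 lists compare with 28 in the highest other split, 8 of 10 giving as many, and the 1 gene with a usage difference with 0, 1 of 10. The real split gave 0 genes, 0 isoforms and 0 KEGG terms in edgeR and camera, so that all 10 splits give as many by construction and the comparison says nothing about chance; the highest other split gave 21, 68 and 41. The split of C1, C4 and T1 against C2, T2 and T3 gave the highest count for each of these except usage. It crosses treatment and divides the libraries by the mean deviation of the disease-associated microglia list. That deviation was -0.58, -1.32 and -0.33 in C1, C4 and T1, and 1.23, 0.38 and 0.63 in C2, T2 and T3. What caused this difference was not tested.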
